A study of Mus musculus with 4 samples.

How the data were processed

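Mammary gland RNA of female nulliparous mice on the FVB background was hybridised to 4 Affymetrix mouse arrays, each carrying 22690 probe sets. The 4 groups were wild-type mice and mice carrying a PPARδ transgene under the mouse mammary tumour virus promoter (MMTV-PPARδ), each kept on standard chow or on chow with GW501516, a synthetic agonist of the nuclear receptor PPARδ, for 1 week. Per the labels' protocols, RNA of 5 mice was pooled for each group, so that each group was 1 array of 1 pool. The labels gave the content of GW501516 in the chow as 0.005% in the protocol and the source names and as 0.001% in a treatment tag, and this conflict could not be settled from the values.

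The deposited values were probe set intensities on a linear scale, which per the labels came from biotin-labelled cRNA prepared by the Affymetrix protocol from 6 µg of RNA. The scanner software, the summarisation algorithm, the detection calls and a genome build were not given in the sources used here. The values were never negative, and their mean without the lowest and highest 2% lay between 500.17 and 500.2 on all arrays, so each array had been scaled to a common trimmed mean. Median intensities were 137.3 for wild type on chow, 144.0 for transgenic on chow, 139.0 for wild type on GW501516 and 137.15 for transgenic on GW501516.

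Genes were named through the platform's probe table, with symbols updated by gene ID through a RefSeq gene table of the mouse. One gene symbol was given for 20393 probe sets, of which 20364 were matched by gene ID, several symbols for 691 probe sets, which named no gene here, and 1606 probe sets were not listed and stayed unnamed. No genomic coordinates were used. For each of 12393 genes the probe set with the highest mean over the 4 arrays was kept. Values below 20.5, the 25th percentile of all values, were set to that floor before log2 was taken, and genes were kept if at least 1 array reached 139, the median of all values, which left 7835 genes. Where one side of a difference lay at the floor, the fold is a lower bound and is written as at least N-fold; where both sides did, no fold is given. The share of values below the floor was 25.3% on both chow arrays, 24.2% for wild type on GW501516 and 25.1% for transgenic on GW501516.

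With 1 array per group there was no replicate spread, so no test, p-value or standard error was computed, and the differences describe these 4 pools. The comparisons were the effect of GW501516 in each genotype, the effect of the transgene on each diet, the combined effect (transgenic on GW501516 against wild type on chow) and the difference between the GW501516 effects in the 2 genotypes. Each was summarised by the number of genes at least 2-fold higher or lower. As the only measure of technical scatter, the kept probe set's change was set against the median change of the gene's other probe sets. Over 2534 genes with at least 2 probe sets, their difference had SDs of 0.34 to 0.45 (log2) in the 4 comparisons between arrays. The SD was 0.54 in the difference of GW501516 effects. Probe sets of a gene share the arrays, so these SDs hold no scatter between arrays. Among differences of at least 2-fold in the named genes, other probe sets went the opposite way for Ighm and Fads2, whose values are not used in the text on single genes. Smaller differences of named genes were not screened in this way. The number of arrays limits the precision of every value.

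For 34 gene lists, the median log2 difference of the measured members was set against 10000 random lists of the same size, matched on mean expression in 10 bins, and described as outside the central 95% or not. Lists with fewer than 5 measured genes, which were the neutrophil list with 4 and the erythroid list with 3, were not set against random lists. About 5% of lists, 1.6 of 32, lie outside by chance if the genes of a list vary independently, which they do not.

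The genes named in the text were Ppard; the 8 highest and the 8 lowest genes of each of the 4 comparisons that differ in 1 factor; the 8 with the largest difference in the same direction in both genotypes or on both diets; the 6 highest and the 6 lowest in the difference of GW501516 effects; up to 4 members of each list with the largest difference in a comparison; and Pdk4, Angptl4, Plin2 and Cpt1a. A further item is not reported here. The groups, comparisons, lists, naming rule, floor, filter and the alternatives in scaling, floor, filter and probe set choice were fixed before the data were examined. An alternative without genes that follow muscle or lymphocyte lists, with a correlation above 0.95 over the 4 arrays, was chosen after seeing the data.

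The steps were tested on simulated data for the GW501516 effect in wild type over 7835 genes with a noise SD of 0.17. Of 100 genes changed by 1.5 on the log2 scale, 99 were recovered at 2-fold, as were all of 100 changed by 3, and 0 of 7635 unchanged genes were called. This checks the computation only: the simulated noise is below the scatter between probe sets and holds no spread between pools or mice, so it says nothing about false calls in this design. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.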

Results

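Gene expression was measured in mammary glands of wild-type and MMTV-PPARδ mice fed chow or chow with GW501516 for 1 week, on 4 arrays of 1 pool each. The design asks what the transgene does on either diet, what the PPARδ agonist does in either genotype, and whether the 2 act together. No difference below has a replicate check.

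Ppard itself was read by 1 probe set. Its intensity was 2.1 in wild type on chow and 1.5 in wild type on GW501516, both below the floor of 20.5. It was 1943 in transgenic mice on chow and 4224 in transgenic mice on GW501516, which is at least 94.8-fold and at least 206-fold higher than in wild type on the same diet. Among the transgenic pools it was 2.17-fold higher on GW501516.

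**Figure D1:**
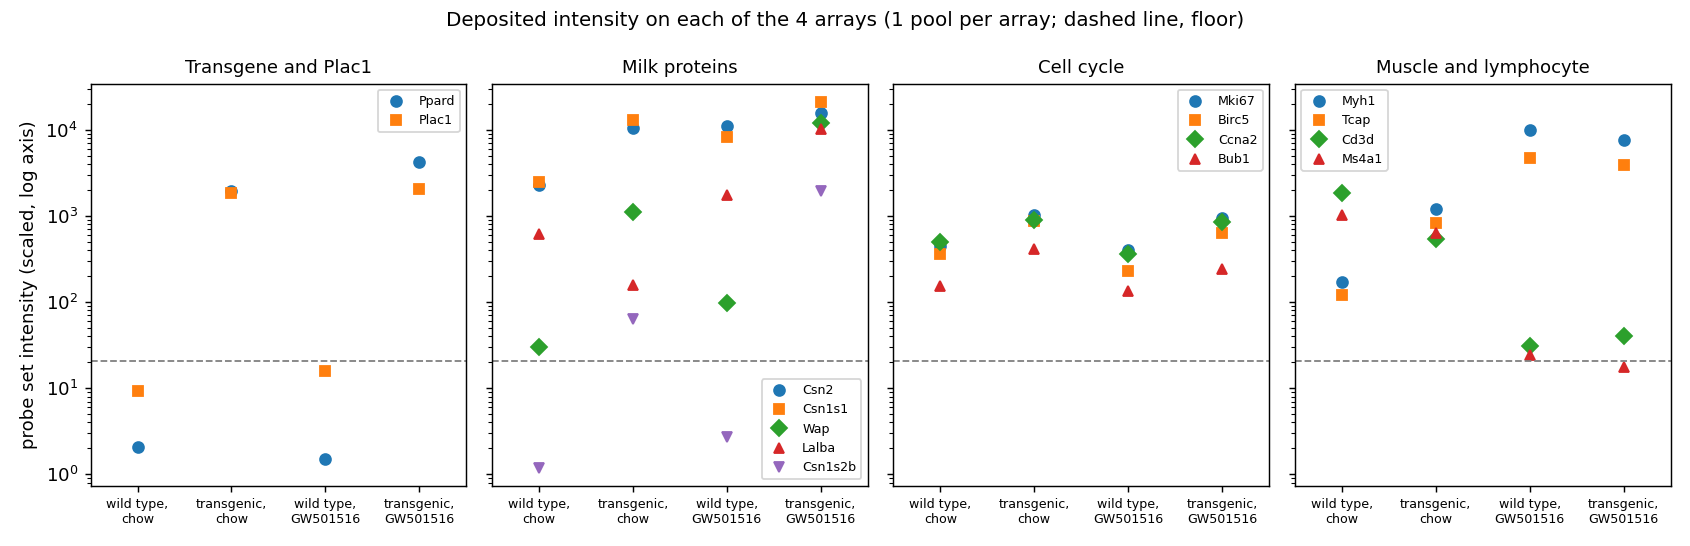
Deposited probe set intensity (log axis) of named genes on each of the 4 arrays; each point is 1 array of 1 pool and the dashed line is the floor of 20.5. Ppard and Plac1 lie below the floor in wild type and between 1823 and 4224 in both transgenic pools, and Wap ranges from 29.8 to 11881.

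In the comparison of genotypes on GW501516, the skeletal muscle list had a median log2 difference of -0.10, inside the central 95%. It lay outside with the mean over probe sets (-0.25), without a filter (-0.19) and under quantile normalization (-0.16). The T cell list had 6 of 12 genes at the floor on both arrays, which sets its median of 0.00, and Cd3e was at least 2.38-fold lower in transgenic mice. Of 7835 genes, 219 were at least 2-fold higher in transgenic mice and 91 at least 2-fold lower. Milk protein genes were among the highest. Wap, the whey acidic protein, was 120-fold higher (98.6 against 11881), Csn1s2b, a casein, at least 95.3-fold and Olah, a thioesterase that releases medium-chain fatty acids for milk fat, at least 93.2-fold. Lalba, the α-lactalbumin of lactose synthesis, was 5.84-fold higher, and Elf5, a transcription factor of the alveolar lineage, 5.04-fold. Of 19 measured milk protein and alveolar genes, 14 were at least 2-fold higher and 0 lower, with a median of 1.81, above all 10000 random lists. Glycam1, which is made by both mammary epithelium and lymph node vessels, was at least 205-fold higher. Its intensity was 9535 and 8128 in wild type and transgenic mice on chow, and 2.2 and 4207 on GW501516.

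Cell cycle genes were higher as a group. All 24 measured members were above 0 on GW501516, 8 of them at least 2-fold, and the median was 0.85. Mki67, a marker of proliferating cells, read 401.4 in wild type and 935.8 in transgenic mice, Birc5 (survivin) was 2.79-fold higher, Kif20a 2.37-fold and Ccna2 (cyclin A2) 2.35-fold. Luminal epithelial markers had a median of 0.33 (0.16 without a filter), with Muc1 7.29-fold higher. Of the 12 basal markers, only Krt14 was at least 2-fold higher, by 8.41-fold, and the median of 0.039 lay inside the central 95% (-0.060 to 0.25 over the processing choices tried).

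Genes outside milk synthesis also separated the genotypes. Plac1, first described in placenta, was at least 101-fold higher, Aqp3, a water and glycerol channel, 68.5-fold, Pigr, the receptor that carries IgA across epithelium, 57.9-fold, and Saa1, an acute-phase protein, 33.9-fold. Slc34a2, a phosphate transporter, was 17.6-fold and Chrdl2, a BMP antagonist, 20.4-fold higher. The lowest genes were Bpifa2 (at least 181-fold lower), Chia1 (at least 28.3-fold), Cst10 (at least 27.2-fold), Smr3a (at least 21.5-fold), Fcgbp (17.0-fold), Dnase1 (at least 13-fold), Fgb (9.48-fold) and Clca3a2 (8.40-fold). Bpifa2, Smr3a and Cst10 are known from salivary glands, and their intensities of 3719, 441.7 and 557.0 in wild type on GW501516 were each below the floor on the other 3 arrays. White adipocyte markers had a median of -0.31, brown adipocyte markers -0.60 and fatty acid and triglyceride synthesis -0.29, with Elovl3 4.03-fold and Elovl6 2.42-fold lower.

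The PPAR target list had a median of 0.050 in this comparison, inside the central 95% (-0.060 to 0.069 over the processing choices tried), with 4 of 24 members at least 2-fold higher. These were Fabp3, a fatty acid binding protein (5.97-fold), Acaa1b, a peroxisomal thiolase (3.26-fold), Acot1, an acyl-CoA thioesterase (2.56-fold), and Ucp3, a mitochondrial uncoupling protein (2.19-fold). Angptl4 (1.38-fold) and Plin2 (1.92-fold) were higher by less than 2-fold and Cpt1a differed by 1.03-fold. Pdk4 was 1.46-fold lower. Milk protein genes, with a median of 1.81, rose in the same comparison, and the PPAR target values were not separated from that rise. Mitochondrial fatty acid oxidation genes had a median of -0.20, with 15 of 18 below 0. This lay outside the central 95% under every scaling, floor, filter and probe set choice tried. In the transgene comparison on chow the median was -0.19, inside the central 95%. On GW501516, white and brown adipocyte markers were lower too, at -0.31 and -0.60, and the fatty acid oxidation values were not separated from this fall.

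The comparison of genotypes on chow had more differences, with 426 genes at least 2-fold higher in transgenic mice and 289 lower. Genes that follow the muscle, T cell or B cell lists made up 16.9% of these, against 0.968% on GW501516. Plac1 was at least 88.9-fold, Wap 36.8-fold, Pigr at least 23.9-fold, Aqp3 15.3-fold, Slc34a2 12.6-fold and Chrdl2 at least 9.08-fold higher. Jchain and Igha, the joining chain and constant region of IgA, were 74.9-fold and 30.3-fold higher, while the plasma cell list had a median of -0.057, which ranged from -0.65 with the stricter filter, outside the central 95%, to 0.29 without a filter. The connexin genes Gjb6 and Gjb2 were at least 64.7-fold and 34.3-fold higher and Bcl2l15 at least 45.9-fold. The lowest genes included Aoc1, diamine oxidase (at least 23.3-fold lower), Ido1, which degrades tryptophan (15.2-fold), Ngfr, a neurotrophin receptor (11.9-fold), Mmd2 (10.3-fold), Dmbt1 (at least 9.92-fold), Greb1, an estrogen-responsive gene (at least 7.27-fold), and Prol1 (at least 7.18-fold).

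Of the milk protein genes, 10 were at least 2-fold higher and 1 at least 2-fold lower on chow, with a median of 1.26 (0.91 to 1.26 over the processing choices tried). Csn2 (β-casein) read 2258 in wild type and 10562 in transgenic mice, and Csn1s1 2490 and 13145, while Lalba was 3.93-fold lower at 624.5 against 159.0. Cell cycle genes had a median of 0.87, with 23 of 24 above 0. Mki67 read 447.5 and 1017, and Bub1 155.0 and 410.6. Luminal markers had a median of 0.75 and 7 of 18 were at least 2-fold higher, among them Ehf (5.88-fold) and Cdh1, E-cadherin (4.03-fold). Krt14 was 11.3-fold and Trp63, a basal transcription factor, 3.497-fold higher.

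Markers of other tissues moved in this comparison. Skeletal muscle genes had a median of 1.45, with 13 of 21 at least 2-fold higher. T cell and B cell markers had medians of -1.65 and -1.01, with Cd3d at 1841 in wild type and 533.1 in transgenic mice. Fibroblast and matrix genes had a median of -0.72, with Col1a1 at 2782 and 1065. Immediate early genes had a median of 0.44, with Fos 7.11-fold and Egr1 3.63-fold higher in the transgenic pool. White adipocyte markers had a median of -0.47. The PPAR target list had a median of -0.082, positive under quantile normalization, with Acot1 6.86-fold, Fabp3 4.71-fold and Acaa1b 4.63-fold higher and Vnn1 2.11-fold lower. Plin2 was 1.52-fold and Cpt1a 1.23-fold higher, and Pdk4 differed by 1.03-fold. The PPAR target values were not separated from the rise of milk protein and skeletal muscle genes in this comparison. The transgenic chow array stood apart in its Gapdh intensity, 2986 against 7171 to 10826 on the other arrays. The control transcript BioB read 32.4 there against 438.1 to 519.0. The larger number of differences on chow was not separated from the departures of this array or from the markers of other tissues.

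The 2 transgene comparisons share no array. Over 7835 genes their log2 differences had a Pearson r of 0.37 and a Spearman rho of 0.26 across genes, which are not independent replicates. On both diets 123 genes were at least 2-fold higher and 17 lower, against 11.9 and 3.36 expected if the 2 sets of genes were independent, and 9 genes went in opposite directions.

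**Figure D2:**
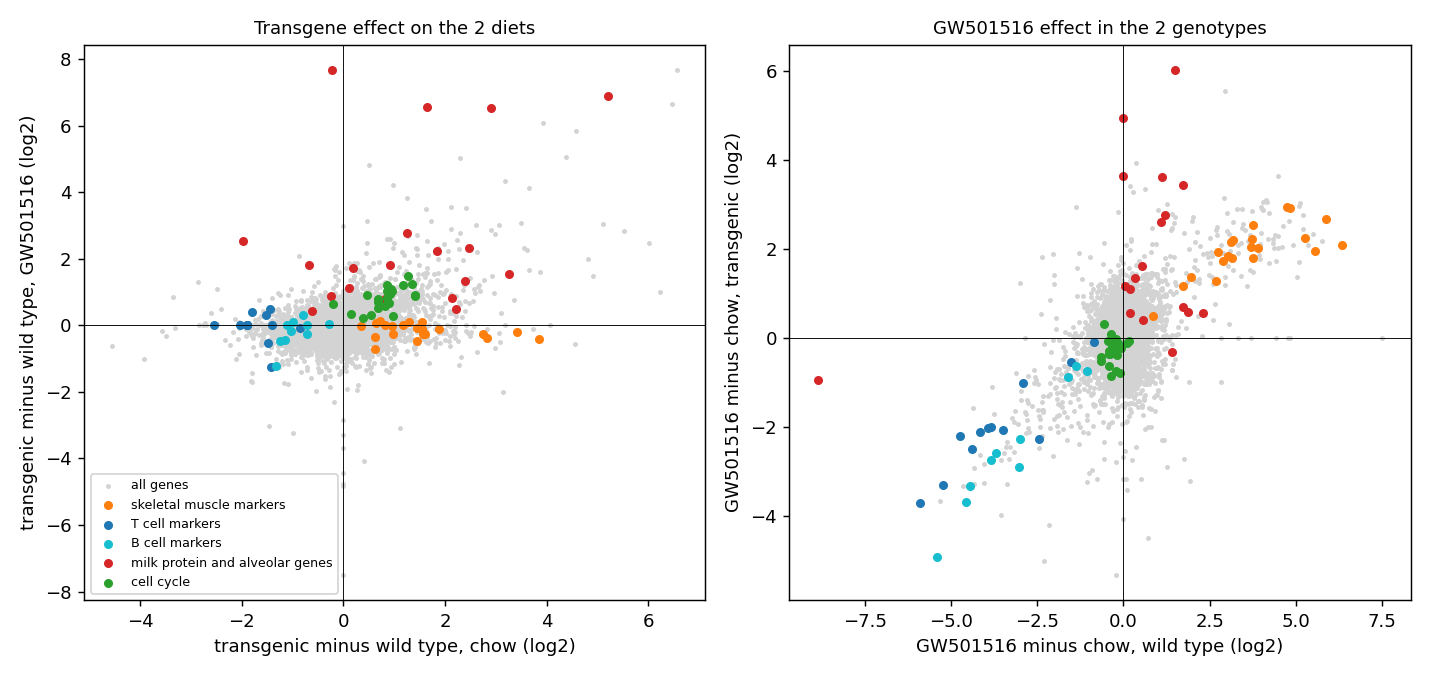
Log2 differences of 7835 genes (grey) with 5 gene lists in colour; left, transgenic minus wild type on chow (x) and on GW501516 (y); right, GW501516 minus chow in wild type (x) and transgenic mice (y). Milk protein (red) and cell cycle genes (green) lie mostly above 0 on the y axis at left, while muscle and lymphocyte genes span the right panel along the diagonal.

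GW501516 in wild-type mice gave 248 genes at least 2-fold higher and 255 lower, and most of its 8 highest and 8 lowest genes were genes of skeletal muscle and of lymphocytes. Myh1, a myosin heavy chain, was 58.2-fold higher (168.9 against 9835), Myh2 at least 81.6-fold, Ckmt2 53.5-fold, Mb (myoglobin) 47.4-fold, Myot 45.2-fold, Smpx 40.9-fold and Tcap (telethonin) 38.4-fold. Of 21 skeletal muscle genes, 20 were at least 2-fold higher and the median was 3.68. In the opposite direction, Cd3d was 59.8-fold lower, Ms4a1 (CD20) 41.9-fold, Ighv14-2 at least 39.99-fold, Cd3g 37.8-fold, Cd8b1 at least 26.9-fold, Ccl5 25.3-fold and Ltb (lymphotoxin β) 23.4-fold. T cell markers had a median of -3.89 and B cell markers -3.37, and 11 of 12 and 10 of 10 were at least 2-fold lower. With a floor at the 40th percentile these medians were -2.24 and -1.91. Genes that follow these 3 lists, picked by their correlation over the same arrays, made up 54.5% of the genes at 2-fold. Without them, an alternative chosen after seeing the data, 129 genes were higher and 100 lower.

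Bpifa2 was at least 181-fold higher and Glycam1 at least 465-fold lower. Milk protein genes had a median of 0.55 (1.08 without a floor) and 9 of 19 were at least 2-fold higher and 1, Glycam1, lower, with Csn2 4.92-fold, Csn1s2a 3.70-fold and Csn1s1 3.33-fold higher. Luminal epithelial markers were higher too, with a median of 0.30 and 15 of 18 above 0. Genes of cholesterol synthesis had a median of 0.54 (0.28 with the mean over probe sets), with 12 of 13 above 0 and Sc5d 2.04-fold higher. Fatty acid and triglyceride synthesis genes had a median of 0.36, with Elovl6, which elongates fatty acids, 2.30-fold higher and Me1 at 5126 and 8948. Cell cycle genes had a median of -0.29 and none was 2-fold lower.

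PPAR target genes had a median of 0.10, just above the central 95% at the percentile of 97.6 and inside it without a filter (97.3) or with quantile normalization (97.4), with Fabp3 2.76-fold and Acaa1b 2.38-fold higher. Skeletal muscle genes, with a median of 3.68, and milk protein genes rose in the same comparison, and the PPAR target values were not separated from that rise. Pdk4, a kinase that limits pyruvate oxidation and a classical PPARδ target, was 1.31-fold higher, Angptl4 1.07-fold lower, Plin2 1.18-fold higher and Cpt1a 1.06-fold higher. Mitochondrial fatty acid oxidation genes had a median of 0.022, negative under quantile normalization.

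GW501516 in transgenic mice gave 310 genes at least 2-fold higher and 318 lower, against the transgenic chow array, on which Gapdh read 2986 against 7171 to 10826 and the control transcript BioB 32.4 against 438.1 to 519.0 on the others. The split of 49.4% higher became 56.7% when arrays were shifted to one median and 53.6% under quantile normalization. Milk genes led the higher side, with Lalba 64.9-fold higher (159.0 against 10325), Lao1, an amino acid oxidase found in milk, 46.6-fold, Csn1s2b 30.6-fold, Olah 12.4-fold, Ltf (lactoferrin) 12.2-fold and Wap 10.8-fold. Ang3 was at least 15.3-fold and Mybph, a muscle gene, 12.4-fold higher. The milk list had a median of 1.17 with 11 of 19 at least 2-fold higher, while the luminal list stood at -0.016, positive under both other scalings. Among the lowest genes were Rspo1, an enhancer of Wnt signalling (40.4-fold), Ubd (32.6-fold), Ms4a1 (at least 30.5-fold), Jchain (22.7-fold), Tnfsf11, the RANK ligand (at least 18.7-fold), Rprm (at least 16.8-fold), Igkv8-30 (15.8-fold) and Cd3d (13.2-fold). This comparison and that of the transgene on chow share the transgenic chow array with opposite sign, and Rspo1, Jchain and Rprm were high on that array (1605, 5161 and 344.7).

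Muscle genes had a median of 2.03, T cell genes -2.10 and B cell genes -2.67, and immediate early genes -0.62. With a floor at the 40th percentile the T cell median was -0.45, inside the central 95%, and the B cell median -0.89, while without a floor the T cell median was -3.32. Glycolysis genes had a median of 0.70, with Pfkm, the muscle form of phosphofructokinase, 3.56-fold higher. White adipocyte markers had a median of 0.35, fatty acid and triglyceride synthesis 0.42, fibroblast and matrix genes 0.47. Under quantile normalization these were 0.16, inside the central 95%, 0.26 and 0.25. Cell cycle genes had a median of -0.27, with 22 of 24 below 0, and lay inside the central 95% with the stricter filter (-0.20). PPAR targets had a median of -0.012, positive when arrays were shifted to one median, with the stricter filter (0.0063) or with the mean over probe sets (0.010). Fabp3 was 3.49-fold and Ucp3 2.68-fold higher, and Pdk4 was 1.09-fold and Cpt1a 1.13-fold lower. Skeletal muscle and milk protein genes rose in the same comparison, and the PPAR target values were not separated from that rise. Plin2 was 1.496-fold higher. Mitochondrial fatty acid oxidation had a median of -0.069, which became 0.0011 when arrays were shifted to one median and -0.13 under quantile normalization, both inside the central 95%. It also lay inside with the mean over probe sets, without a filter, and without probe sets that can share transcripts.

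The 2 GW501516 comparisons share no array. Their log2 differences had a Pearson r of 0.51 and a Spearman rho of 0.22 across genes. In both genotypes 149 genes were at least 2-fold higher and 120 lower, against 9.81 and 10.3 expected if the 2 sets were independent, and 19 went opposite ways. The 8 genes with the largest shared difference were Ms4a1, Cd3d, Ltb, Ighv14-2, Mybph, Igkv8-30, Pou2af1 and Ccl5, of which all but Mybph are genes of lymphocytes or of immune recruitment. Without the genes that follow the muscle or lymphocyte lists, 77 genes were at least 2-fold changed in the same direction in both genotypes. No number expected under independence was computed for this set, so the 77 cannot be set against one.

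**Figure D3:**
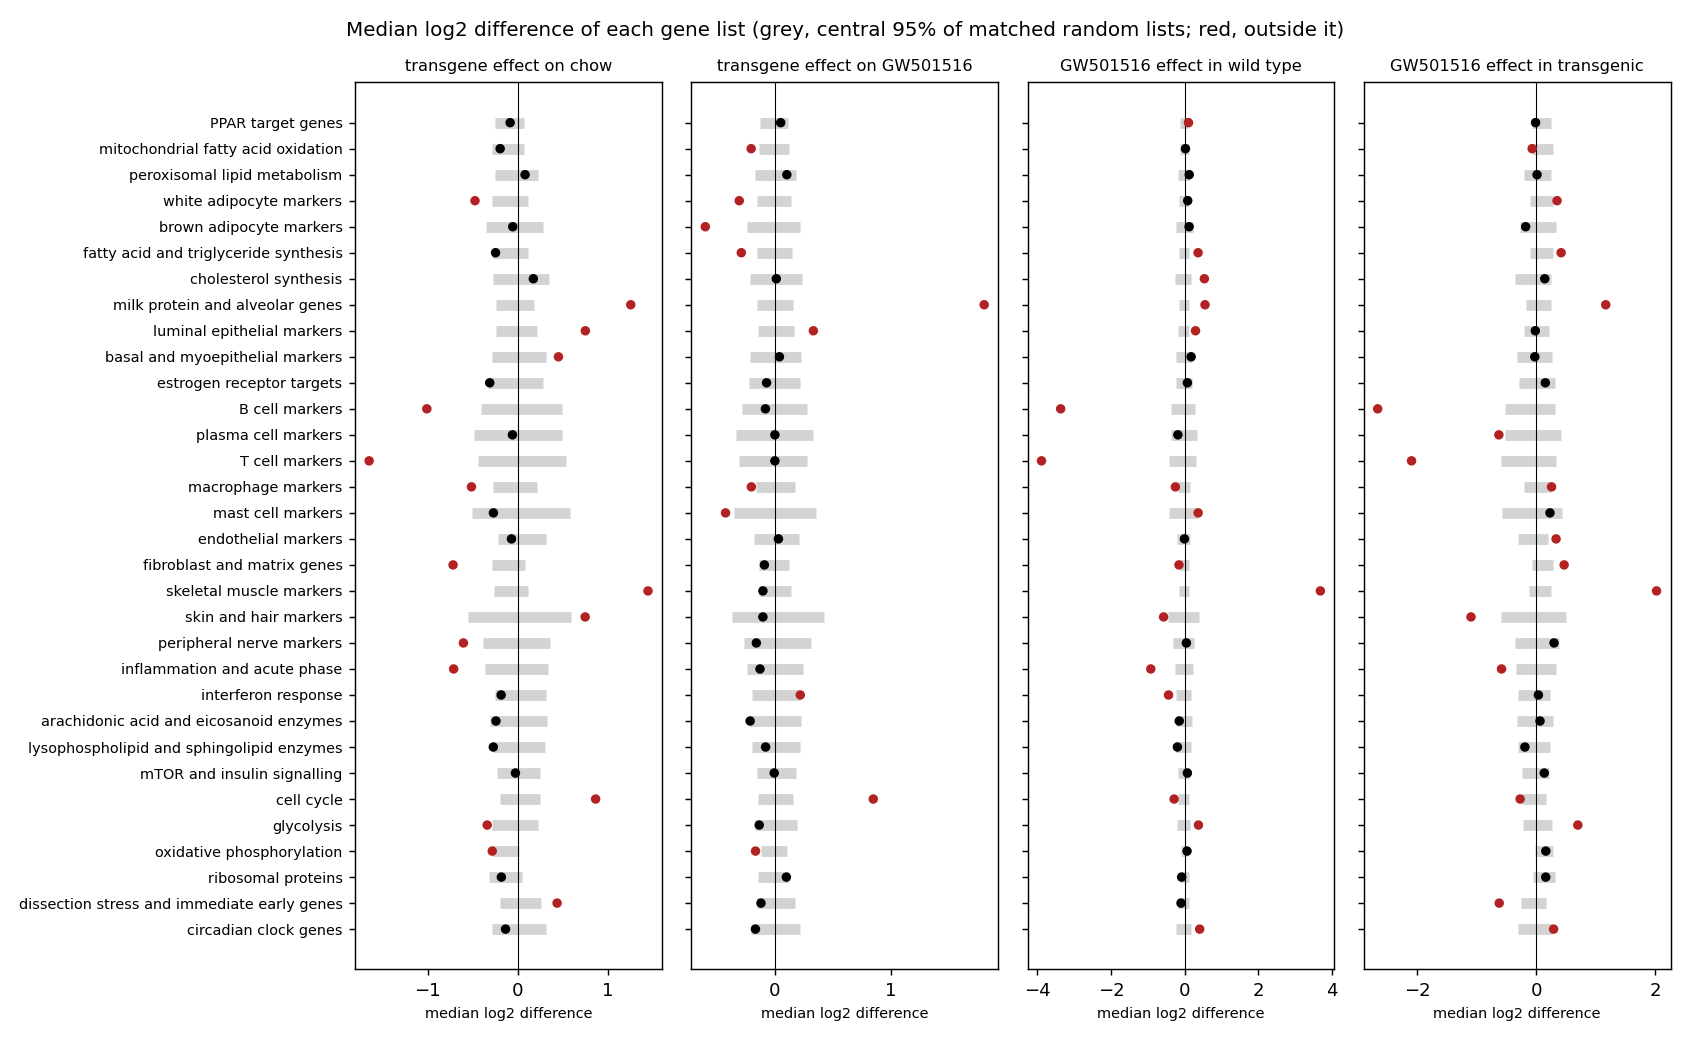
Median log2 difference of each gene list in 4 comparisons; grey bars span the central 95% of 10000 matched random lists and red points lie outside. Milk protein and cell cycle lists lie far outside in both transgene comparisons, at 1.26 and 1.81 and at 0.87 and 0.85. In both GW501516 comparisons they lie outside too, at 0.55 and 1.17 and at -0.29 and -0.27. Skeletal muscle lies far outside in both GW501516 comparisons, at 3.68 and 2.03, and with the transgene on chow, at 1.45.

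The GW501516 effects differed between genotypes by at least 2-fold for 753 genes, 345 with a higher and 408 with a lower signed log2 effect in transgenic mice, a split of 45.8% higher that became 56.1% when arrays were shifted to one median. Among the 6 highest, Lalba (a log2 difference of 4.52), Scnn1g, an epithelial sodium channel subunit (4.32), and Mmd2 (4.22) were measured above the floor on all arrays. Glycam1 (at least 7.91) and Greb1 (at least 4.16) have bounds, and Csn1s2b was at the floor on both wild-type arrays. Among the 6 lowest, Jchain (-5.21), Elovl3 (-5.15) and Rspo1 (-5.12) were measured on all arrays, while Bpifa2, Chia1 and Cst10 were at the floor on both transgenic arrays, so that no difference is given. Milk protein genes had a median of 1.06 but went both ways, with 11 of 19 at least 2-fold higher and 4 lower, which were Csn2 (-1.74), Muc15 (-1.73), Csn1s2a (-1.31) and Csn1s1 (-1.06). The chow intensities of Csn2 and Csn1s1 given above for transgenic mice compare with a highest intensity of 14309 on that array. On the transgenic GW501516 array the highest intensity was 21072. Whether a limit at the top of the scale lowered these differences was not tested. Skeletal muscle genes had a median of -1.43. The difference combines 4 arrays, so a departure of any single array enters it. Its SD between probe sets was 0.54, above the 0.34 to 0.45 of the comparisons that differ in 1 factor. The count of 753 genes can therefore not be set directly against the counts of those comparisons.

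Transgenic mice on GW501516 against wild type on chow had 426 genes at least 2-fold higher and 328 lower. Milk protein genes had a median of 2.89 and 15 of 19 were at least 2-fold higher and 1, Glycam1, lower, cell cycle genes of 0.55, and luminal markers of 0.53. Skeletal muscle genes had a median of 3.51, T cell genes of -3.81 and B cell genes of -3.72, and the last pair was -2.24 and -2.03 with a floor at the 40th percentile. Plin2 was 2.27-fold and Angptl4 1.30-fold higher and Pdk4 1.12-fold lower.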

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

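The gene and list differences in the next paragraph are opposite in sign in the 2 genotypes or on the 2 diets by at least 2-fold for a gene, or lie outside the central 95% on both sides for a list. They were not tested, since each value rests on single arrays, and covering every named gene with this rule was chosen after the values were seen. Of the tests of explanations below, those of GW501516 alone, of scaling, of more epithelium and of the transgene with either diet were chosen after the result was seen.

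For the GW501516 effect, the median of macrophage markers was -0.25 in wild type and 0.26 in transgenic mice, a difference of 0.51, and that of fibroblast and matrix genes -0.15 and 0.47, a difference of 0.62. In transgenic mice the macrophage median was inside the central 95% under quantile normalization (0.19) and with the mean over probe sets (0.20), and the fibroblast median was 0.25 under quantile normalization. Genes higher in wild type and lower in transgenic mice were Elovl3 (difference of -5.15), Fcgbp (-4.48), Clca3a2 (-4.18), Igha (-3.44), Fos (-2.92) and Cdh1 (-2.17). Genes lower in wild type and higher in transgenic mice were Scnn1g (4.32), Mmd2 (4.22) and Ngfr (3.42), and, with the transgenic chow array at the floor, Greb1 (at least 4.16), Aoc1 (at least 3.91), Dmbt1 (at least 3.22) and Sprr1a (at least 3.18). For the transgene effect, Lalba was lower on chow and higher on GW501516 (4.52), as were Greb1 (at least 4.16) and Ang3 (at least 3.58), and Elovl3 (-5.15) and Clca3a2 (-4.18) went the other way. Each difference of the transgene effects between diets equals that of the GW501516 effects between genotypes, since both are formed from the same 4 arrays.

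Lymphocyte genes were lower on the other arrays than on the wild-type chow array. The T cell list was already lower by a median of -1.65 in transgenic mice on chow, where neither pool had GW501516, with quartiles of -1.89 and -1.43, which argues against GW501516 as the only cause. Ribosomal proteins had a median of -0.082 with GW501516 in wild type. All arrays had been scaled to a common trimmed mean, so a large shift of this list was unlikely in advance. The value argues only against a shift of all genes together. Lymph node tissue in the wild-type chow pool may be the source: 5 measured genes of lymph node stroma and sinus had a median of -0.85, between the bounds set in advance, so this cannot be told apart from a change of lymphocytes within the gland.

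Skeletal muscle genes were higher on the other arrays than on the wild-type chow array. A further 14 muscle genes were listed before their values were seen. In the GW501516 effect in wild type their median was 3.44, with quartiles of 3.13 and 3.92. The main muscle list already stood at 3.68 there, so a rise was likely with muscle tissue in the pools and with induced muscle genes alike. This test does not separate the 2. Myh1 and Tcap read 9835 and 4691 on the wild-type GW501516 array. The main muscle list was also higher by 1.45 in transgenic mice on chow, with quartiles of 0.81 and 1.61, which argues against GW501516 as the only cause. An effect of GW501516 on muscle gene expression, with or without muscle tissue in the pools, stays open.

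Milk protein genes were higher after GW501516 in transgenic mice. Their median exceeded that of luminal markers by 1.19, and the lower quartile of 0.56 lay above the luminal median of -0.016, which argues against more epithelium in the pool as the only cause. Ribosomal proteins had a median of 0.16, negative under quantile normalization. As for the lymphocyte genes, this argues only against a shift of all genes together. The transgene effect on the milk list was 1.26 on chow (0.91 to 1.26 over the processing choices tried) and 1.81 on GW501516, and Ppard was 2.17-fold higher in the transgenic pool on GW501516, so a higher transgene level cannot be told apart from GW501516 itself. The transgenic chow pool is the baseline, its array stood apart in BioB (32.4 against 438.1 to 519.0) and Gapdh (2986 against 7171 to 10826), and this and the stage of the estrous cycle, not analysed here, stay open.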

How the results depend on the processing

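One alternative, leaving out genes that follow the muscle, T cell or B cell lists, was chosen after the results were seen; all others were planned. The counts of genes at 2-fold stayed within 1.5 times, and the 2 correlations across genes kept their sign, under a shift of the arrays to one median, quantile normalization, no floor, a floor at the 40th percentile, the mean over a gene's probe sets, and without probe sets that can share transcripts. Counts moved by more than 1.5 times where the number of genes tested changed. With the filter at the 70th percentile, GW501516 in wild type gave 158 genes higher and 124 lower, the transgene on chow 253 and 165, GW501516 in transgenic mice 202 and 157, the combined effect 280 and 159, and the difference of GW501516 effects 196 and 230; the transgene on GW501516 gave 44 lower, and 152 genes differed the same way by GW501516 in both genotypes. Without a filter, 395 were lower with GW501516 in wild type, 147 with the transgene on GW501516 and 516 in the combined effect, and the difference of GW501516 effects had 530 higher and 624 lower. Without the follower genes, the GW501516 effect in wild type had 129 higher and 100 lower, the combined effect 166 lower, and 77 genes differed the same way by GW501516. Of the lists outside the central 95%, 3 of 17 with GW501516 in wild type, 3 of 16 with the transgene on chow, 9 of 17 with GW501516 in transgenic mice, 3 of 11 with the transgene on GW501516, 10 of 21 in the combined effect and 6 of 13 in the difference lay inside it under at least 1 alternative. Of the lists inside it, in the same order, 4 of 15, 6 of 16, 4 of 15, 5 of 21, 2 of 11 and 8 of 19 lay outside under at least 1. Of the medians of the lists outside, 4 reversed and the cause was not tested: mitochondrial fatty acid oxidation with GW501516 in transgenic mice became 0.0011 after the shift to one median, plasma cell markers in the combined effect 0.49 with the mean over probe sets, inflammation genes with the transgene on chow 0.19 without a filter, and circadian genes in the combined effect -0.031 with the stricter filter. The milk list was above all random lists under every scaling, floor, filter and probe set choice tried, with a median of 1.76 to 1.83 for the transgene on GW501516. Dim genes are limited by the floor: 88 genes lay at it on at least 1 array. No paired analysis was possible because each group was 1 array of 1 pool.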

Other observations

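No test in this part was chosen after a result was seen, since it gives values only. Genes of the circadian clock had a median of 0.41 for GW501516 in wild type and 0.29 in transgenic mice, the second inside the central 95% without a filter (0.13), with the mean over probe sets (0.14) or with the stricter filter (0.23), with Per2 at 217.1 on chow and 401.1 on GW501516 in wild type and Arntl, its activator, at 100.9 and 56.1. The transgene comparisons gave -0.13 on chow and -0.17 on GW501516, inside the central 95%. Inflammation and acute-phase genes had medians of -0.92 with GW501516 in wild type and -0.71 with the transgene on chow, which became -0.15 and 0.19 without a filter, and their members diverged: Ccl5 read 3633 and Ccl8 2903 in wild type on chow and 143.6 and 860.6 on GW501516, while Saa1, Saa2 and Lcn2 were highest in transgenic mice on GW501516 at 2794, 1025 and 9490. Interferon response genes had a median of -0.44 with GW501516 in wild type and 0.22 with the transgene on GW501516, the second inside the central 95% with the mean over probe sets (0.087), quantile normalization (0.20) or the stricter filter (0.24).

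Skin and hair markers, of which 5 were measured, had medians of 0.75 with the transgene on chow and -1.10 with GW501516 in transgenic mice, both 0.00 without a filter, and Krt15 read 947.5 on the transgenic chow array and 114.3 on the transgenic GW501516 array. Mast cell markers had a median of 0.37 with GW501516 in wild type and -0.43 with the transgene on GW501516, both inside the central 95% with the mean over probe sets (0.31 and -0.36). Nerve markers had a median of -0.60 with the transgene on chow, and endothelial markers 0.33 with GW501516 in transgenic mice. Oxidative phosphorylation genes had medians of -0.28 and -0.17 with the transgene on chow and on GW501516, the first inside the central 95% under quantile normalization (-0.084), with the mean over probe sets (-0.25) or with the stricter filter (-0.28). Ribosomal proteins lay inside the central 95% in all 4 comparisons that differ in 1 factor. Peroxisomal lipid genes, eicosanoid and lysophospholipid enzymes, mTOR and insulin signalling, and estrogen receptor targets did so with the main processing only, and each lay outside it in at least 1 of these comparisons under another choice.

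The control transcript BioB, spiked in at hybridisation, read 32.4 in its middle probe set on the transgenic chow array against 438.1 to 519.0 on the other arrays, while Cre read 7135 there against 9717 to 11058. The ratio of 3' to 5' Gapdh probe sets was 1.12 on that array and 0.774 to 0.900 on the others. Array pairs correlated at 0.876 to 0.947 across genes on the log2 scale.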
